A study of Mus musculus with 15 samples.

How the data were processed

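Total RNA from flash-frozen kidneys was labelled and hybridised to Affymetrix Mouse Gene 2.0 ST arrays, 1 mouse per array, per the labels. The labels' protocols give 100 ng of RNA per array and RNA integrity numbers above 7. The deposited values are on the log2 scale, as RMA gives them, and per the submitters' processing notes and the series design text they were made with Partek 6.6 and RMA, which corrects background, normalizes between arrays and summarises probes. That the scale is log2 was taken from the values, which lie between 1.04 and 13.12. The genome build behind the array's annotation is not given in the sources used here, so no coordinates are given.

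The table held 41345 entries on 15 arrays with no missing value. Of these, 23521 were paired with 1 gene symbol in the platform's annotation, 1814 with several and 16010 with none. Symbols were checked by Entrez identifier against the RefSeq gene table of GRCm38.p6, where 23328 entries matched and 193 kept the platform's symbol. Only entries with 1 symbol were tested under a name. Where a gene had several entries (1082 genes), the one with the highest mean over all arrays was used, which left 22180 genes, and no filter on dim genes was applied. The arrays measure hybridisation, so no depth applies, and the number of arrays limits the precision.

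Groups were taken from the titles and genotype labels. A linear model with 4 group means was fitted to all 15 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, and 5 contrasts were tested: Cre+ against Cre- at 4 months and at 7 months, the difference of these effects, and 7 against 4 months within each genotype. Tests were two-sided, with Benjamini-Hochberg adjustment over 22180 genes and a threshold of 0.05. Errors given with log2 changes are standard errors from this fit. The submitters named an analysis of variance, and limma was used in its place because groups held 3 or 4 mice, with the plain linear model without moderation as an alternative. The series design text counts mice, so p-values measure the spread between animals.

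Before the data were examined, 30 gene lists were fixed, covering lysosome, V-ATPase, autophagy, folliculin and Rag GTPase, TFE3 carcinoma, RET, NRF2, metabolic, cell cycle, injury, matrix and interferon genes, markers of nephron segments and of other cell types a kidney sample can hold, and genes that report sex. They were not chosen on these samples. Of 406 members 366 were measured. No blood marker was measured under 1 symbol, so blood content was not analysed here, and the female-biased list had 2 measured members, under the minimum of 3, which left 28 lists. Each was tested with camera at a preset correlation of 0.01, adjusted over the lists, and also with an estimated correlation and with fry. In the lists that were not called, median, mean and test differed in sign for 3 lists at 4 months, 3 at 7 months, 4 in the interaction, 3 in the age comparison of Cre- and 5 in that of Cre+ kidneys.

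Genes named in the text followed a rule fixed at the same time. Tfe3, Prcc, Cdh16, Gpnmb, Ctsk, Ret, Havcr1, Lcn2 and Mki67 were given whatever their values. For each Cre comparison the 10 largest rises and 10 largest falls with no overlap between groups could be named, predicted genes excepted, with up to 3 rising and 3 falling members per list (where none passed, at most 2 as values), the 5 largest in each direction of the interaction and the 3 largest of each age comparison. The text names fewer than the rule allows.

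Alternatives fixed beforehand were a filter keeping genes above the median of all named entries in at least 3 arrays, quantile normalization, median centring, trend and robust variance, the plain linear model, fits of 2 groups only, array weights, the replicate number as a block, the mean of Y-linked genes as a covariate, the mean of a gene's entries, all entries of the table, and each array left out in turn. Fits within arrays of high or of low Y-linked values were added after the data were seen. The procedure was tested on simulated data of 22180 genes, with noise independent between genes and far fewer changed genes than were called at 7 months. The rates that follow hold for that setting and are not error rates of the real comparisons. For the 4-month comparison it recovered 40%, 93.9% and 100% of genes changed by 0.5, 1 and 2 on the log2 scale, with 8 false calls, and for the 7-month comparison 21.3%, 91.2% and 100%, with 7 false calls. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.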

Results

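Whole kidneys were profiled from mice carrying a PRCC-TFE3 knock-in at the Rosa26 locus, behind a stop cassette flanked by sites that Cre recombinase removes. PRCC-TFE3 is a fusion of a splicing-associated protein and a transcription factor of the MiT family, and it is found in a form of renal cell carcinoma. Cre came from the KSP-Cre transgene, whose promoter is that of Cdh16 (Ksp-cadherin), a cadherin of kidney tubule epithelium. The groups were 4 Cre-negative (Cre-) and 4 Cre-positive (Cre+) mice at 4 months and 3 Cre- and 4 Cre+ mice at 7 months, with 1 array per mouse. The 15 arrays had median log2 values between 4.40 and 4.55. Pairs of arrays from one group correlated at 0.983 to 0.994 across genes and pairs from different groups at 0.958 to 0.994, and the first principal component held 46.4% of the variance. The number of arrays limits the precision of every value given here.

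The labels do not give the sex of the mice. Y-linked genes (mean of the measured members) were at 6.92 or above in 8 arrays and at 2.98 or below in 7, and each group held both kinds, 2 and 2 in each group except for 2 high and 1 low among the 7-month Cre- arrays. Over arrays of both kinds, the 3 Y-linked genes had a median difference between Cre+ and Cre- of -0.20 at 4 months and -0.73 at 7 months (adjusted p = 0.717 and 0.843), and the 4 measured male-biased kidney genes had medians of -0.30 and -1.9 (adjusted p = 0.626 and 0.336), with 0 members past the test, also when adjusted over the list alone. The 2 measured female-biased genes were too few for a list test. Slc7a12, an amino acid transporter, was 1.38 higher on the log2 scale in Cre+ kidneys at 4 months (SE 1.16, adjusted p = 0.62) and 1.25 higher at 7 months (SE 1.26, adjusted p = 0.54). Abcc3, an efflux transporter, was 0.28 higher (SE 0.97, adjusted p = 0.93) and 0.86 higher (SE 1.05, adjusted p = 0.63).

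Comparisons within the arrays of high and of low Y-linked values were chosen after the data were seen. In the 4 arrays with high values at each age, the male-biased gene Slco1a1, an anion transporter, fell by 2.20 at 4 months (SE 0.21, adjusted p = 3.2e-05) and by 3.38 at 7 months (SE 0.21, adjusted p = 2.2e-07). The other 3 male-biased genes did not pass there at 4 months: Cyp7b1 was at -0.66 (adjusted p = 0.26), Slc7a13 at -0.43 (adjusted p = 0.67) and Kap at -0.18 (adjusted p = 0.93). At 7 months Cyp7b1 fell by 1.32 (SE 0.28, adjusted p = 0.0047) and Slc7a13 by 1.38 (SE 0.40, adjusted p = 0.026), and Kap was at -0.33 (adjusted p = 0.77). The arrays with low values were 2 Cre- and 2 Cre+ at 4 months but 1 Cre- and 2 Cre+ at 7 months, so the spread behind the 7-month tests comes mostly from other groups, and the single control limits them. With that limit Kap was at -2.70 there at 7 months (SE 0.75, adjusted p = 0.027), and Cyp7b1 was at 1.12 at 4 months (adjusted p = 0.058) and 0.59 at 7 months (adjusted p = 0.32). Slco1a1 had means of 2.40 to 3.28 there, near the Y-linked level of the same arrays, so no change is read from it. Abcc3 was at 0.90 at 4 months (adjusted p = 0.12) and rose by 1.34 at 7 months (SE 0.29, adjusted p = 0.0048) in the arrays with high values, and was at -0.33 (adjusted p = 0.60) and -0.60 (adjusted p = 0.31) in those with low values. Slc7a12 rose by 2.96 (SE 0.31, adjusted p = 7.6e-05) and 2.19 (SE 0.31, adjusted p = 2e-04) in the arrays with high values, and was at -0.20 (adjusted p = 0.79) and -1.01 (adjusted p = 0.093, or 0.0091 when only the arrays with low values were fitted, against 1 control in both fits) in those with low values.

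The table has no detection calls. Xist, which is silent in males, stood at 3.35 to 3.93 in the arrays with high Y-linked values, and the Y-linked mean was at 2.98 or below in the others. A gene at such a level in one group may not be above background there, so its fold may be a lower bound and the order of such folds is not fixed. Among the genes named in the comparisons that follow, Cre- means were at most 3.93 at both ages for Moxd1, Tyrp1, Mmp7, Adgrg2, Nmrk2, Akr1b8, Slc7a11, Ms4a1 and Mc2r, and Lep had means of 3.84 and 3.66 in Cre- and Cre+ kidneys at 4 months and of 3.44 in Cre+ kidneys at 7 months. The Cre- mean of Diras2 at 7 months was close to that level, at 4 (SD 0.63), so its fold may be a lower bound too.

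Transcripts of the fusion's partner genes were examined first. Tfe3 was at 6.5 in Cre- and 6.53 in Cre+ kidneys at 4 months, a log2 difference of 0.03 (SE 0.09, n = 4 and 4, adjusted p = 0.92). At 7 months the difference was 0.22 (SE 0.10, n = 3 and 4, adjusted p = 0.14). Prcc differed by 0.09 (SE 0.12, adjusted p = 0.78) at 4 months and by -0.25 (SE 0.13, adjusted p = 0.20) at 7 months. Where the probes lie relative to the fusion junction, and whether they detect the human or mouse sequence of the knock-in, is not given in the sources used here, so these values check neither the presence nor the absence of the fusion. Cdh16, whose promoter drives Cre, differed by -0.17 (SE 0.12, adjusted p = 0.55) at 4 months and was 1.35-fold lower at 7 months (log2 change -0.43, SE 0.13, adjusted p = 0.026).

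The first comparison asked what differed between Cre+ and Cre- kidneys at 4 months. No group carried KSP-Cre without the knock-in, so effects of PRCC-TFE3 and of the Cre transgene itself cannot be told apart. Gpnmb, a glycoprotein of lysosomes and melanosomes, rose 78.7-fold in Cre+ kidneys (log2 change 6.30, SE 0.17, n = 4 and 4, adjusted p = 1.5e-13). Large rises were also found for Moxd1, a copper monooxygenase relative (5.69, SE 0.21), Diras2, a small GTPase (5.61, SE 0.22), and Reln, a secreted matrix glycoprotein (5.06, SE 0.12), which rose 51.7-fold, 48.7-fold and 33.3-fold. Tgfb2, a growth factor, rose 24.1-fold, P2rx7, an ATP-gated channel, 17.6-fold, and Tyrp1, an enzyme of melanin synthesis, 16.6-fold. Cd68, a lysosomal glycoprotein much used as a macrophage marker, rose 14.5-fold (3.86, SE 0.21, adjusted p = 3e-09). Nr4a1, a nuclear receptor, and Ngfr, a neurotrophin receptor, rose 12.5-fold and 11.4-fold. Ret, a receptor tyrosine kinase, rose 5.76-fold (2.53, SE 0.17, adjusted p = 5.1e-08), Ctsk, a lysosomal cysteine protease, 1.84-fold (0.88, SE 0.15, adjusted p = 0.0026), Lcn2, a secreted injury marker, 3.66-fold (1.87, SE 0.33, adjusted p = 0.0028), and Mki67, a proliferation marker, 2.41-fold (1.27, SE 0.17, adjusted p = 0.00029). Havcr1, another tubule injury marker, was 1.21 higher (SE 0.37, adjusted p = 0.094).

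Among the largest falls at 4 months, Nccrp1 fell by 1.92 on the log2 scale (3.77-fold lower, SE 0.34, adjusted p = 0.0033), Pcsk6, a proprotein convertase, by 1.83 (3.55-fold lower, SE 0.17), Gpx6, a glutathione peroxidase, by 1.66 (3.15-fold lower, SE 0.19), Wfdc15b by 1.61 (3.04-fold lower, SE 0.21) and Dnase1, a nuclease, by 1.04 (2.06-fold lower, SE 0.20, adjusted p = 0.0064).

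Of the 28 gene lists tested at 4 months, 16 were called, 11 upward and 5 downward, and 2 of the calls held with an estimated correlation between genes. The human TFE3 renal carcinoma markers were one of these. Of its 9 measured members 5 rose and 0 fell, the same counts when adjusted over the list alone, with a median log2 change of 0.46 (adjusted p = 1.16e-11, and adjusted p = 0.000748 with an estimated correlation). The members that rose included Gpnmb, Tyrp1 and Rragd, a Rag GTPase of amino acid signalling (1.20, SE 0.11, adjusted p = 4.9e-06). The other was the cell cycle list, where 6 of 24 measured members rose and 0 fell (17 and 0 adjusted over the list alone), with a median of 0.40 (adjusted p = 8.5e-12, and adjusted p = 0.0298 with an estimated correlation). Besides Mki67, Top2a, a topoisomerase, rose 2.34-fold (1.22, SE 0.20) and Kif11, a spindle motor, 1.82-fold (0.86, SE 0.14).

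Lysosome and mTORC1-related lists rose at 4 months. In the lysosome genes of the CLEAR network, 8 of 31 rose and 0 fell (9 and 1 adjusted over the list alone), with a median of 0.16 (adjusted p = 7.26e-05, and adjusted p = 0.215 with an estimated correlation). Hexa, a subunit of hexosaminidase, rose 3.43-fold (1.78, SE 0.13), Ctsl, a cysteine protease, 1.95-fold (0.96, SE 0.12) and Gla, a galactosidase, 1.68-fold (0.75, SE 0.12). Beside these, macrophage and monocyte markers had a median of 0.56 in the same arrays. Among 9 folliculin and Rag GTPase genes 4 rose and 0 fell (5 and 0 adjusted over the list alone), with a median of 0.29 (adjusted p = 1.45e-05, and adjusted p = 0.0722 with an estimated correlation). Rragc rose 1.51-fold (0.59, SE 0.11) and Fnip2, a folliculin partner, 1.45-fold (0.53, SE 0.09). Of 14 V-ATPase subunits 1 rose, Atp6v0a1 (0.75, SE 0.10), and 0 fell (2 and 0 adjusted over the list alone), with a median of 0.12 (adjusted p = 0.0375, and adjusted p = 0.465 with an estimated correlation). Autophagy genes were not called (adjusted p = 0.987). In that list 1 of 17 rose, Sqstm1, an autophagy receptor (0.44, SE 0.11), and 1 fell, Wipi1 (-0.41, SE 0.10), with 2 and 1 adjusted over the list alone.

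Injury, matrix and immune lists also rose at 4 months, and each lost its call with an estimated correlation. Kidney injury genes had 8 of 20 rising and 0 falling (12 and 0 adjusted over the list alone), with a median of 0.52 (adjusted p = 1.07e-10, and adjusted p = 0.0722 with an estimated correlation). Fgg, a fibrinogen chain, rose 2.86-fold (1.52, SE 0.22), and Vcam1, an adhesion molecule, 1.89-fold (0.92, SE 0.20). Extracellular matrix and myofibroblast genes had 7 of 22 rising and 0 falling (8 and 0 adjusted over the list alone), with a median of 0.34 (adjusted p = 8.95e-06, and adjusted p = 0.308 with an estimated correlation). Col1a1, a collagen, rose 2.50-fold (1.32, SE 0.20) and Thbs1, a matricellular protein, 2.01-fold (1.01, SE 0.20). Macrophage and monocyte markers had 5 of 17 rising and 0 falling (15 and 0 adjusted over the list alone), with a median of 0.56 (adjusted p = 1.16e-11, and adjusted p = 0.0722 with an estimated correlation). Mrc1, a mannose receptor, rose 2.43-fold (1.28, SE 0.15) and Lyz2, a lysozyme, 2.28-fold (1.19, SE 0.22). In the interferon response list 2 of 10 rose, Isg15 (0.61, SE 0.16) and Cxcl10 (0.50, SE 0.11), and 0 fell, as adjusted over the list alone, with a median of 0.37 (adjusted p = 0.00185, and adjusted p = 0.308 with an estimated correlation). In the lymphocyte list 1 of 11 rose, Cd3g (0.74, SE 0.17), and 0 fell (2 and 0 adjusted over the list alone), with a median of 0.28 (adjusted p = 0.0103, and adjusted p = 0.386 with an estimated correlation).

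Markers of several nephron segments were lower at 4 months. Among 18 proximal tubule markers 0 rose and 3 fell (0 and 7 adjusted over the list alone), with a median of -0.36 (adjusted p = 6.21e-10, and adjusted p = 0.0722 with an estimated correlation). In the same arrays the median of the macrophage and monocyte markers was 0.56. The markers that fell were Gatm, a creatine synthesis enzyme (-0.81, SE 0.21), Slc5a2, the glucose transporter SGLT2 (-0.78, SE 0.14), and Slc34a1, a phosphate transporter (-0.38, SE 0.10). Distal convoluted tubule markers had 0 of 10 rising and 2 falling (0 and 4 adjusted over the list alone), with a median of -0.34 (adjusted p = 2.13e-05, and adjusted p = 0.282 with an estimated correlation), and the members that fell were Wnk4, a kinase of salt transport (-0.84, SE 0.14), and Trpm6, a magnesium channel (-0.67, SE 0.16). Thick ascending limb markers had 1 of 9 rising and 3 falling (2 and 3 adjusted over the list alone), with a median of -0.13 (adjusted p = 0.042, and adjusted p = 0.457 with an estimated correlation). Egf, a growth factor made in that segment, fell by 0.77 (SE 0.16) and Bsnd, a chloride channel subunit, by 0.57 (SE 0.13), whereas Cldn19, a tight junction protein, rose by 0.89 (SE 0.17). Podocyte markers had no member past the test, with a median of -0.30 (adjusted p = 0.00177, and adjusted p = 0.286 with an estimated correlation). Principal cell markers had 1 of 9 rising, Aqp3, a water channel (1.01, SE 0.11), and 0 falling (2 and 0 adjusted over the list alone), with a median of 0.27 (adjusted p = 0.0253, and adjusted p = 0.316 with an estimated correlation).

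Among the metabolic lists at 4 months, oxidative phosphorylation genes had 0 of 31 rising and 1 falling (0 and 3 adjusted over the list alone), with a median of -0.18 (adjusted p = 4.88e-11, and adjusted p = 0.0722 with an estimated correlation). The member that fell was Ndufb3, a complex I subunit (-0.51, SE 0.12). Beside these, proximal tubule markers had a median of -0.36 and macrophage and monocyte markers of 0.56 in the same arrays. Fatty acid oxidation genes were not called (adjusted p = 0.0523, 1 of 12 rising and 1 falling, the same adjusted over the list alone). Their median was -0.12 and their mean 0.15, with Pdk4, a pyruvate dehydrogenase kinase, up by 1.48 (SE 0.26) and Ppara, a nuclear receptor of lipid metabolism, down at -0.52 (SE 0.13). Glycolysis genes were not called (adjusted p = 0.42), but Hk2, a hexokinase, rose 3.92-fold (1.97, SE 0.25) and Pfkp, a phosphofructokinase, 2.19-fold (1.13, SE 0.17), and the count of 2 rising among 11 was the same adjusted over the list alone. RET pathway genes (adjusted p = 0.922, with Ret alone of 16 passing), NRF2 targets (adjusted p = 0.755, 0 of 13), intercalated cell markers (adjusted p = 0.622, with Atp6v0d2, a proton pump subunit, at 0.59 the 1 of 11 passing), endothelial markers (adjusted p = 0.717, 0 of 10), adipocyte markers (adjusted p = 0.25, 0 of 6), urothelium markers (adjusted p = 0.626, with Upk1a, a uroplakin, at 1.10 the 1 of 5 passing) and adrenal cortex markers (adjusted p = 0.717, 0 of 5) were not called, with the same counts adjusted over the list alone.

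In all, 606 genes were higher and 178 lower in Cre+ kidneys at 4 months, of 22180 tested, and 149 and 11 of these changed at least 2-fold. Each array centred on its median gave 492 higher and 435 lower, so that the share of higher calls was 77.3% as deposited and 53.1% after centring. The Cre+ and Cre- values did not overlap for 729 of the 784 called genes, and for 9.5% of all genes against 2.86% by chance. Of 55 gene results called and named here, 14 lost the call under another planned setting or without 1 array: Atp6v0d2, Bsnd, Cd3g, Cldn19, Cxcl10, Gatm, Isg15, Ndufb3, Ppara, Slc34a1, Sqstm1, Trpm6, Vcam1 and Wipi1. Without Cre- replicate 1, Cre- replicate 3, Cre+ replicate 3 or Cre+ replicate 4 the higher genes numbered 384, 385, 373 or 370, and without Cre- replicate 1, Cre- replicate 3, Cre+ replicate 2 or Cre+ replicate 3 the lower genes numbered 86, 84, 72 or 96. The call of Havcr1 was gained with the Y-linked covariate or with the 2 groups fitted alone, and the second table entry of Cldn19 stood at -0.08.

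**Figure D1:**
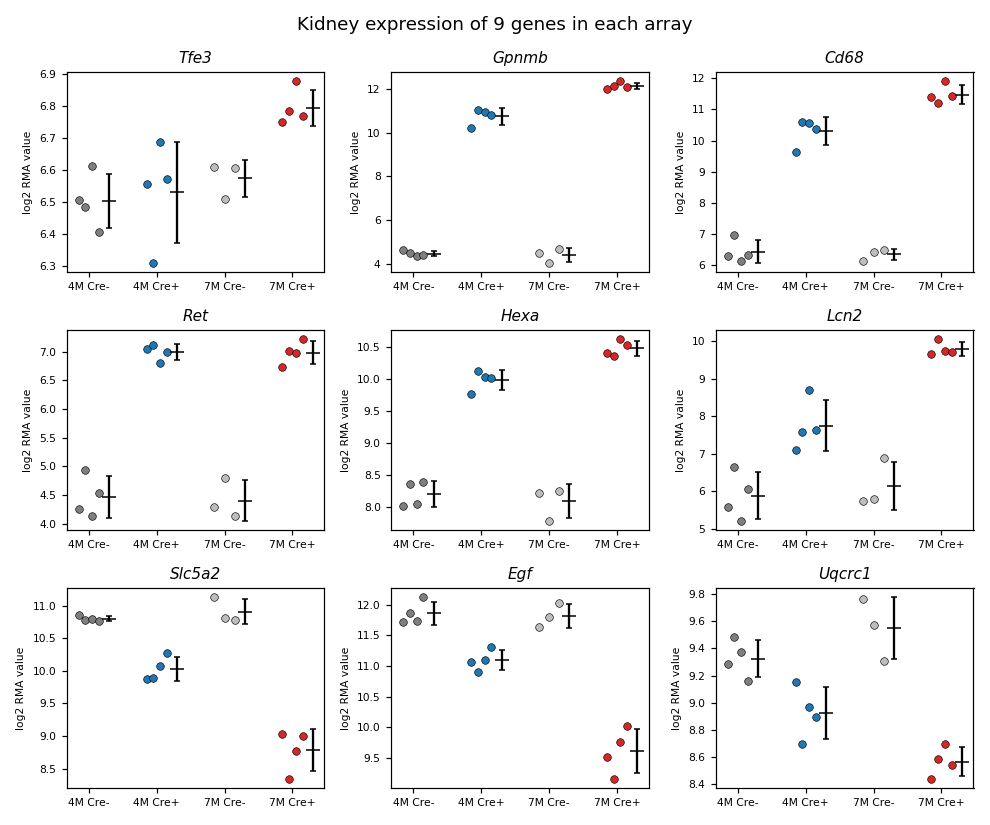
Log2 RMA values of 9 genes in each array (points), by group on the horizontal axis, with the group mean and SD as bars. Each panel has its own vertical scale. Gpnmb, Cd68, Ret and Hexa were higher in every Cre+ array than in any Cre- array at both ages, and Slc5a2 and Egf were lower, while Tfe3 differed by 0.03 at 4 months.

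The second comparison put the same question at 7 months. Gpnmb rose 214-fold (log2 change 7.74, SE 0.18, n = 3 and 4, adjusted p = 3.2e-14). Diras2 rose 102-fold (6.67, SE 0.24), Moxd1 43.4-fold (5.44, SE 0.22), Reln 37.4-fold (5.22, SE 0.13), Cd68 35-fold (5.13, SE 0.23) and Tyrp1 27.1-fold (4.76, SE 0.28). Tgfb2, P2rx7 and Nr4a1 rose 24.3-fold, 23.7-fold and 18.1-fold. Mmp7, a matrix metalloproteinase, rose 15.9-fold (3.99, SE 0.30), and its second, dimmer table entry stood at -0.10. Ret rose 5.96-fold (2.58, SE 0.19) and Ctsk 1.97-fold (0.98, SE 0.17). Lcn2 rose 12.5-fold (3.64, SE 0.35, adjusted p = 1.4e-06), Havcr1 7.76-fold (2.96, SE 0.40, adjusted p = 3.9e-05) and Mki67 2.63-fold (1.39, SE 0.19, adjusted p = 3.7e-05).

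Among the largest falls at 7 months, Cyp2d12, a cytochrome P450, fell by 3.21 (9.23-fold lower, SE 0.47, adjusted p = 9.1e-05), Dnase1 by 2.89 (7.39-fold lower, SE 0.22), Wfdc15b by 2.63 (6.18-fold lower, SE 0.23), Slc22a7, an organic anion transporter, by 2.55 (5.87-fold lower, SE 0.39), Sectm1b by 2.53 (5.76-fold lower, SE 0.21), Hsd3b2, a steroid dehydrogenase, by 2.51 (5.68-fold lower, SE 0.35) and Gpx6 by 2.50 (5.65-fold lower, SE 0.20).

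Proximal tubule markers led the lists that fell. All 18 measured members fell, also when adjusted over the list alone, with a median of -1.34 (adjusted p = 1.71e-17, and adjusted p = 0.0206 with an estimated correlation). Gatm fell by 2.18 (SE 0.23), Slc5a2 by 2.12 (SE 0.15) and Acsm2, a mitochondrial acyl-CoA synthetase, by 1.76 (SE 0.41). In oxidative phosphorylation genes 0 of 31 rose and 28 fell (0 and 30 adjusted over the list alone), with a median of -0.62 (adjusted p = 1.38e-16, and adjusted p = 0.0206 with an estimated correlation). Uqcrc1, a complex III subunit, fell by 0.98 (SE 0.13) and Ndufa9, a complex I subunit, by 0.86 (SE 0.10). Fatty acid oxidation genes had 1 of 12 rising and 8 falling (1 and 9 adjusted over the list alone), with a median of -0.60 (adjusted p = 0.000237, and adjusted p = 0.089 with an estimated correlation). Ppara fell by 1.19 (SE 0.14) and Ehhadh, a peroxisomal enzyme, by 1.13 (SE 0.16), whereas Pdk4 rose by 1.72 (SE 0.28). In the same arrays the median of the macrophage and monocyte markers was 1.5 and that of the lymphocyte markers 1.10.

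Markers of other nephron segments were lower too. Distal convoluted tubule markers had 0 of 10 rising and 8 falling, the same adjusted over the list alone, with a median of -0.80 (adjusted p = 0.00011, and adjusted p = 0.236 with an estimated correlation). Calb1, a calcium-binding protein, fell by 1.61 (SE 0.22) and Wnk4 by 1.29 (SE 0.15). Intercalated cell markers had 0 of 11 rising and 9 falling, the same adjusted over the list alone, with a median of -0.72 (adjusted p = 0.000177, and adjusted p = 0.273 with an estimated correlation). Insrr, a receptor kinase, fell by 1.19 (SE 0.19) and Slc26a4, the anion exchanger pendrin, by 1.08 (SE 0.20). Thick ascending limb markers had 1 of 9 rising and 4 falling (2 and 5 adjusted over the list alone), with a median of -0.39 (adjusted p = 0.00856, and adjusted p = 0.288 with an estimated correlation). Egf fell by 2.21 (SE 0.17) and Bsnd by 1.25 (SE 0.14), and Cldn19 rose by 0.75 (SE 0.19) while its second table entry stood at -0.39. Podocyte markers had 0 of 7 rising and 4 falling (0 and 5 adjusted over the list alone), among them Podxl (-0.77, SE 0.19) and Nphs1 (-0.76, SE 0.15), both of the filtration barrier, with a median of -0.47 (adjusted p = 0.0321, and adjusted p = 0.403 with an estimated correlation). Endothelial markers were not called (adjusted p = 0.264), with 0 of 10 rising and 3 falling (0 and 5 adjusted over the list alone), Ehd3 at -1.41 (SE 0.23) and Flt1, a VEGF receptor, at -0.53 (SE 0.14). Principal cell markers were not called (adjusted p = 0.768), and Aqp3 alone of the 9 passed, at 0.73 (SE 0.12), as adjusted over the list alone.

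Kidney injury genes rose in 17 of 20 members at 7 months and fell in 0 (18 and 0 adjusted over the list alone), with a median of 1.19 (adjusted p = 3.29e-17, and adjusted p = 0.0206 with an estimated correlation). Fgb rose by 3.61 (SE 0.39) and Fgg by 3.56 (SE 0.24), both genes of fibrinogen chains. Every one of the 17 macrophage and monocyte markers rose, also when adjusted over the list alone, with a median of 1.5 (adjusted p = 1.47e-18, and adjusted p = 0.0206 with an estimated correlation), with Lyz2 at 2.21 (SE 0.23) and Ms4a7 at 1.99 (SE 0.25) after Cd68. Lymphocyte markers had 8 of 11 rising and 0 falling (9 and 0 adjusted over the list alone), with a median of 1.10 (adjusted p = 8.39e-08, and adjusted p = 0.0806 with an estimated correlation). The T cell receptor components Cd3g (2.16, SE 0.19) and Cd3e (1.89, SE 0.19) and the B cell gene Ms4a1 (1.56, SE 0.24) were among them. Extracellular matrix and myofibroblast genes had 15 of 22 rising and 0 falling (18 and 0 adjusted over the list alone), with a median of 0.85 (adjusted p = 9.95e-12, and adjusted p = 0.089 with an estimated correlation). Col1a1 rose by 2.43 (SE 0.21), Col3a1 by 2.09 (SE 0.22) and Fn1, fibronectin, by 2.03 (SE 0.36). Interferon response genes had 8 of 10 rising and 0 falling, the same adjusted over the list alone, with a median of 0.74 (adjusted p = 0.000162, and adjusted p = 0.168 with an estimated correlation). Irf7, an interferon regulatory factor, rose by 1.16 (SE 0.19) and Usp18 by 0.95 (SE 0.16).

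The lysosome list had 14 of 31 members rising and 3 falling at 7 months (15 and 3 adjusted over the list alone), with a median of 0.30 (adjusted p = 3.75e-06, and adjusted p = 0.089 with an estimated correlation). Hexa rose 5.25-fold (2.39, SE 0.14), Ctsl 3.14-fold (1.65, SE 0.13) and Gla 2.69-fold (1.43, SE 0.13), whereas Lipa, the lysosomal acid lipase, was 2.21-fold lower (-1.14, SE 0.12) and Neu1, a sialidase, 1.68-fold lower (-0.75, SE 0.16). Beside these, macrophage and monocyte markers had a median of 1.5 and proximal tubule markers of -1.34 in the same arrays. Folliculin and Rag GTPase genes had 4 of 9 rising and 1 falling (5 and 1 adjusted over the list alone), with a median of 0.28 (adjusted p = 0.0096, and adjusted p = 0.20 with an estimated correlation). Rragd rose by 1.5 (SE 0.12), Rragc by 0.72 (SE 0.11) and Fnip2 by 0.64 (SE 0.10). Human TFE3 renal carcinoma markers had 6 of 9 rising and 0 falling (6 and 1 adjusted over the list alone), with a median of 0.98 (adjusted p = 1.93e-06, and adjusted p = 0.0144 with an estimated correlation). Nmrk2, a nicotinamide riboside kinase, rose by 1.69 (SE 0.35) and Sqstm1 by 0.74 (SE 0.12). Cell cycle genes had 18 of 24 rising and 0 falling (21 and 0 adjusted over the list alone), with a median of 0.56 (adjusted p = 3.66e-11, and adjusted p = 0.0206 with an estimated correlation), with Top2a at 1.81 (SE 0.22) and Kif11 at 1.29 (SE 0.15). Urothelium markers had 4 of 5 rising and 0 falling, the same adjusted over the list alone, with a median of 0.91 (adjusted p = 0.000725, and adjusted p = 0.089 with an estimated correlation). Upk1a rose by 1.89 (SE 0.18) and Upk1b by 1.29 (SE 0.26).

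Other lists were not called at 7 months, although single members passed. V-ATPase subunits had 4 of 14 rising and 2 falling (4 and 3 adjusted over the list alone, adjusted p = 0.291), with Atp6v0a1 at 1.28 (SE 0.11). Autophagy genes had 4 of 17 rising and 1 falling (5 and 1 adjusted over the list alone, adjusted p = 0.336). Among NRF2 targets 3 of 13 rose and 3 fell, the same adjusted over the list alone (adjusted p = 0.843). Akr1b8, an aldo-keto reductase, rose by 1.24 (SE 0.25) and Slc7a11, the cystine transporter, passed with means of 2.74 and 3.74, too dim for a size to be read, whereas Osgin1 fell by 1.32 (SE 0.15) and Gsr, glutathione reductase, by 0.55 (SE 0.13). Glycolysis genes had 3 of 11 rising and 1 falling (3 and 3 adjusted over the list alone, adjusted p = 0.791), with a median of -0.19 and a mean of 0.32. Hk2 rose 8.98-fold (3.17, SE 0.27) and Pfkp 2.75-fold (1.46, SE 0.18). RET pathway genes had 1 of 16 rising, Ret, and 2 falling, Dusp6, a phosphatase (-0.57, SE 0.19), and Gfra1, a RET co-receptor (-0.54, SE 0.13), as adjusted over the list alone (adjusted p = 0.843). Adipocyte markers had 1 of 6 falling, Lep, the gene of leptin (-0.81, SE 0.12, list adjusted p = 0.0835), and adrenal cortex markers had 1 of 5 falling, Mc2r, the ACTH receptor (list adjusted p = 0.827), as adjusted over the list alone. The means of Mc2r were 3.08 in Cre- and 2.61 in Cre+ kidneys, too dim for a change to be read.

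At 7 months 2597 genes were higher and 2394 lower in Cre+ kidneys, 681 and 450 of them at least 2-fold, and 17 of 28 lists were called, 10 upward and 7 downward, of which 6 held with an estimated correlation. The share of higher calls was 52% as deposited, 43.2% with each array centred on its median (2441 higher and 3208 lower) and 45.1% with quantile normalization (2544 and 3102). Values did not overlap for 4648 of the 4991 called genes, and for 29.2% of all genes against 5.71% by chance. Of 80 gene results called and named here, those of Cdh16, Cldn19, Dusp6 and Gfra1 lost the call under another planned setting or without 1 array.

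**Figure D2:**
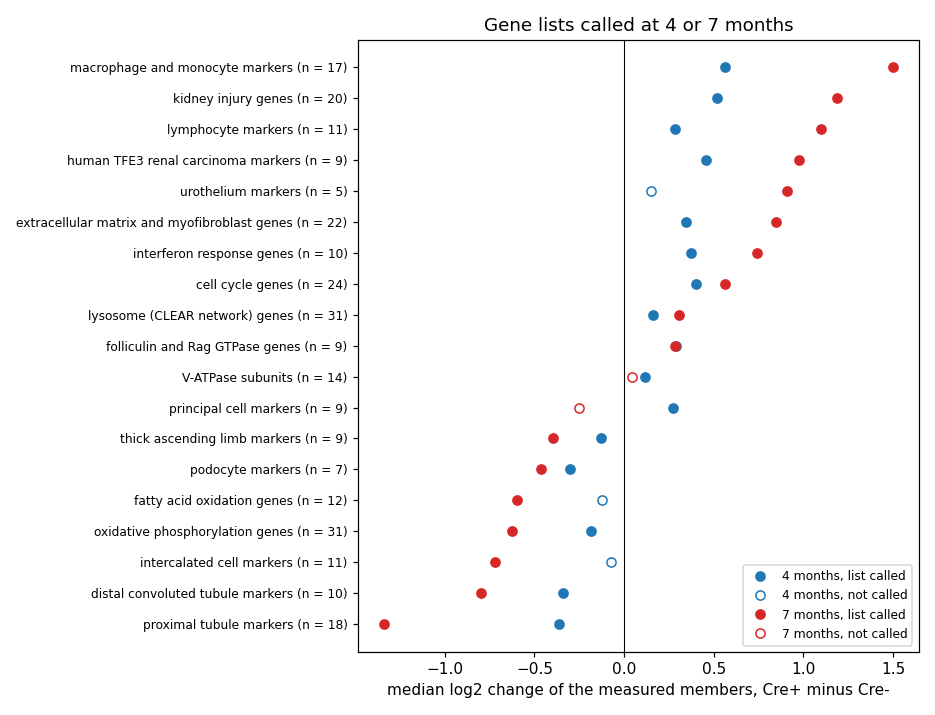
Median log2 change (Cre+ minus Cre-, horizontal axis) of the measured members of the 19 gene lists called at either age, with the number of measured members. Filled points are called lists at 4 months (blue) and 7 months (red), and open points are not called. Proximal tubule markers lay at -0.36 and -1.34, and macrophage and monocyte markers at 0.56 and 1.5.

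The 4-month and 7-month effects of Cre, which rest on different arrays, were then compared across the 22180 genes, which are not independent replicates. The log2 changes correlated at r = 0.748 (Spearman's rho 0.559). There were 547 genes higher at both ages, against 71 for independent lists, 168 lower at both, against 19.2, and 0 called in opposite directions, against 86.3. Of the genes called at 4 months, 595 of 606 higher genes and 177 of 178 lower genes had a change of the same sign at 7 months, and the median ratio of the 7-month to the 4-month log2 change over these calls was 1.46.

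The difference between the Cre effects at the 2 ages was tested as an interaction, the 7-month effect minus the 4-month effect. Gabrp, a GABA receptor subunit, had a log2 change of 0.34 at 4 months and 2.99 at 7 months, a difference of 2.65 (SE 0.27, adjusted p = 0.00046). Adgrg2, an adhesion receptor, differed by 2.53 (SE 0.27, adjusted p = 0.00046), Hpse, heparanase, by 2.51 (SE 0.30, adjusted p = 0.00098), Mmp7 by 2.38 (SE 0.41, adjusted p = 0.0069) and Fgb by 2.31 (SE 0.53, adjusted p = 0.031). In the other direction, Cyp2d12 differed by -3.12 (SE 0.65, adjusted p = 0.019), Slc22a26 by -2.58 (SE 0.64, adjusted p = 0.046), Dnase1 by -1.85 (SE 0.30, adjusted p = 0.0049), Sectm1b by -1.76 (SE 0.29, adjusted p = 0.0058) and F13b, a coagulation factor subunit, by -1.72 (SE 0.25, adjusted p = 0.0037). The list calls numbered 16 of 28, 9 upward and 7 downward. Kidney injury genes (5 of 20 higher, 12 adjusted over the list alone, median 0.80) and proximal tubule markers (10 of 18 lower, 18 adjusted over the list alone, median -0.98) held with an estimated correlation, each at adjusted p = 0.0347.

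The interaction was past the threshold for 213 higher and 262 lower genes, 136 and 101 of them at least 2-fold. After median centring the higher genes were the more numerous (297 against 256), and after quantile normalization the lower ones (250 against 326). Of 100 splits of the arrays 9, the real one included, gave at least the 475 genes found, and the 8 others kept the 7-month labels (7 splits) or relabelled 6 of the 7 arrays at that age, so the splits do not decide whether chance gives this count. The calls of Cyp2d12, Fgb, Mmp7 and Slc22a26 were lost under another planned setting or without 1 array. Leaving out 1 array gave 108 to 228 higher and 117 to 288 lower genes, the lowest of each without 7-month Cre- replicate 2.

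The arrays at 7 months were then compared with those at 4 months within each genotype. In Cre+ kidneys, age and a longer time under Cre cannot be told apart. In Cre- kidneys (n = 4 and 3) limma called 1 gene higher at 7 months and 0 lower, Gm7609, a predicted gene chosen for naming after its value was seen (log2 change 0.98, SE 0.13, adjusted p = 0.026), with 600 genes at an unadjusted p under 0.05, and 0 genes were called by the plain linear model without moderation or with the 2 groups fitted alone. The call was lost without any one of the 7 Cre- arrays and without 7-month Cre+ replicate 1 or 4. Oxidative phosphorylation genes were the 1 list called, with a median of 0.08 and 0 of 31 members past the test, the same adjusted over the list alone (adjusted p = 0.00934, and adjusted p = 0.861 with an estimated correlation).

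In Cre+ kidneys (n = 4 and 4) the age comparison gave 914 higher and 1488 lower genes at 7 months, 172 and 127 of them at least 2-fold. Gabrp rose by 2.83 (SE 0.19, adjusted p = 6.7e-07), and the immunoglobulin light chain segments Igkv4-72 and Igkv15-103, members of a multigene family whose probes can share sequence, rose by 2.82 (SE 0.63) and 2.80 (SE 0.53). Slc22a26, an organic ion transporter, fell by 2.32 (SE 0.44), Hpd, an enzyme of tyrosine breakdown, by 2.19 (SE 0.39) and Cyp2d12 by 2.03 (SE 0.44). There were 17 list calls, 9 upward and 8 downward, and 4 held with an estimated correlation, each at adjusted p = 0.0184. They were the kidney injury genes (14 of 20 rising, 18 adjusted over the list alone, median 0.80), the macrophage and monocyte markers (15 of 17 rising, 17 adjusted over the list alone, median 1.01), the urothelium markers (4 of 5 rising, as adjusted over the list alone, median 0.79) and the proximal tubule markers (18 of 18 falling, as adjusted over the list alone, median -1.02). Leaving out 4-month Cre+ replicate 1 gave 604 higher genes, and leaving out 4-month Cre+ replicate 4 or 7-month Cre+ replicate 2 gave 959 or 956 lower genes.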

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

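The tests of Cd68, of the other macrophage markers, of the proximal tubule markers and of a mixture with RNA of the other sex were chosen after the results were seen. The splits of the arrays were fixed before. The tests of general loss and of a shift of sex-biased genes were written before their own results were seen. They use comparisons within Y-linked levels, however, which were chosen after the data were seen. The interaction tests are those of the 7-month minus the 4-month effect of Cre.

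Cd68 rose far more than other macrophage and monocyte markers. Its log2 change was above that of the next marker by 2.57 at 4 months (Mrc1, 1.28) and by 2.92 at 7 months (Lyz2, 2.21). These were gaps of 9.89 and 8.94 standard errors, with the errors of both genes taken as independent although they share arrays. The gaps argue against added macrophages that raise every marker by the same log2 amount as the only source of the Cd68 rise. Markers can differ in probe response and in signal from other cells, so unequal rises do not exclude added macrophages as that source. Whether added macrophages differ in their Cd68 level was not tested. For the other 16 markers, 16 of which rose at 7 months with a median of 1.5, more macrophages may be the source. A lower share of proximal tubule RNA would raise markers of every other cell type alike. Medians at 7 months were -0.345 for endothelial, -0.466 for podocyte, -0.394 for thick ascending limb and -0.796 for distal convoluted tubule markers. They were -0.723 for intercalated cell, -0.253 for principal cell and -0.73 for adipocyte markers. Lymphocyte (1.10), urothelium (0.907), matrix (0.847) and adrenal cortex (0.0326) lists had positive medians. This argues against a lower share as the only source, but a part of the rise from it is not excluded. A change in what the resident cells express stays open and was not tested.

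Proximal tubule markers fell together at 7 months. With the Y-linked covariate 18 of 18 still fell, which argues against an imbalance of sex. The list's median moved by at most 0.0538 under median centring or quantile normalization. The deposited values were already normalized between arrays, with medians of 4.40 to 4.55, so these steps could move the list little. The fall thus does not rest on differences in median left between the arrays. Scaling made before or by RMA was not tested. The falls with the covariate ranged from -2.23 (Gatm, SE 0.20) to -0.68 (Aqp1, SE 0.12), a difference of 1.56. Heterogeneity Q was 122 on 17 degrees of freedom, with genes taken as independent although they share arrays. The markers thus did not fall by the same log2 amount. Markers can differ in probe response and in signal from other cells, so the test does not decide whether a uniform loss of proximal tubule RNA was the cause. Lower expression within remaining cells, or an uneven loss of segments, may each be at work, and neither was tested.

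Genes that differ between control arrays with high and low Y-linked values moved in Cre+ arrays. Defined in the controls of one age and tested at the other, 116 male-biased genes had a median of -1.22 at 7 months and 88 had -0.795 at 4 months in the 4 arrays with high Y-linked values at each age. In the arrays with low values (4 at 4 months, 3 at 7 months, of which 1 is a control assumed to vary like the others) the medians were -0.312 and 0.126. Male-biased genes were chosen for being lower in control arrays with low values, so they had less room to fall in those arrays. The medians thus do not show that the fall was limited to the arrays with high values. The female-biased genes (59 and 46) had medians of 0.138 and 0.374 in the arrays with high values. They were chosen for being lower in control arrays with high values, so they had less room to fall there. Whether a general loss took place is thus not decided by them. In the arrays with low values their medians were -0.597 and -0.217, each at percentile 0, after rounding, of 10000 matched random lists. Such lists measure the sampling of genes and not the spread between mice. The genes defined in the 7-month controls rest on 1 control with low values. In the arrays with high values Xist changed by at most -0.368, which argues against mixing with RNA of the other sex. A shift away from the male pattern (-0.795 the smaller of its medians) may explain the arrays with high values, where Slc7a12 stood at 2.96 (SE 0.31, adjusted p = 7.6e-05) and 2.19 (adjusted p = 2e-04), but a loss of each sex's own pattern goes with the values too, was not tested and stays open (the Cre effect differed between Y-linked levels for 13 genes at 4 months and 12 at 7 months).

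Other splits of the arrays gave fewer genes than the real one in most comparisons. At 4 months the real split gave 784 genes and the highest other split 6 (1 of 35 as large), and with the Y-linked covariate 1099 and 3 (1 of 35). At 7 months the values were 4991 and 1839 (1 of 35), and with the covariate 5322 and 2262 (1 of 35). For age in Cre+ kidneys they were 2402 and 3 (1 of 35). In each of these the real split gave the most genes, and 1 of 35 is the smallest share that 35 splits allow. That argues against chance but does not exclude it. The highest other split at 7 months without the covariate set Cre+ replicates 2, 3 and 4 against the rest, so it kept most of the real grouping. For age in Cre- kidneys 5 of 35 splits gave as many genes as the 1 found. A split following the Y-linked level gave 586 there, which points to a structure of the samples, so nothing argues against chance for that count.

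For the interaction 9 of 100 splits, the real one included, gave at least the 475 genes found, with 4182 the highest. Of the 8 other such splits, 7 left 0 of the 7 arrays at 7 months relabelled while relabelling 2 to 6 of the 8 at 4 months, and 1 relabelled 2 of 8 and 6 of 7. Splits that keep one age's labels, or nearly swap them, carry that age's Cre effect into the difference, so they give no chance value and the splits leave open whether chance gives this count.

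In the interaction 16 lists were called. The higher medians were 0.166 for the lysosome genes, 0.298 for the TFE3 renal carcinoma markers, 0.146 for the cell cycle genes, 0.796 for the kidney injury genes, 0.478 for the matrix and myofibroblast genes, 0.331 for the interferon genes, 0.979 for the macrophage markers, 0.868 for the lymphocyte markers and 0.737 for the urothelium markers. The lower medians were -0.417 for oxidative phosphorylation, -0.522 for fatty acid oxidation, -0.981 for the proximal tubule, -0.426 for the thick ascending limb, -0.483 for the distal convoluted tubule, -0.472 for the principal cells and -0.648 for the intercalated cells. With an estimated correlation the injury genes and the proximal tubule markers kept the call.

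Of the genes named in the text, those past the test of the difference between the ages with a Cre effect higher at 7 months were Gpnmb (1.45), Cd68 (1.27), Ctsl (0.68), Fgg (2.05), Fgb (2.31), Vcam1 (2.30), Cd3g (1.42), Cd3e (1.35), Ms4a1 (1.45), Ms4a7 (1.43), Mmp7 (2.38), Col3a1 (1.19), Upk1b (1.62), Gabrp (2.65), Adgrg2 (2.53) and Hpse (2.51). Those past it with a lower effect were Dnase1 (-1.85), Gatm (-1.36), Slc5a2 (-1.34), Slc34a1 (-0.96), Egf (-1.45), Cyp2d12 (-3.12), Sectm1b (-1.76), Lipa (-0.84), Osgin1 (-0.94), Ndufa9 (-0.65), Ehhadh (-0.98), Slc26a4 (-1.17), Lep (-0.63), Slc22a26 (-2.58) and F13b (-1.72). For Lep and Ms4a1, 3 of the 4 group means were at 3.84 or below, a level that may not be above background, so the sizes of their differences are not fixed.

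Single arrays stood apart from the other 3 of their group in 12 of 309 pairs of gene and group over 103 genes, where chance gives about 1 in 20. In 4-month Cre+ replicate 1, Nccrp1 was at 5.25 (others 3.98 to 4.14), Cd3g at 4.48 (5.16 to 5.21) and Ms4a1 at 3.46 (3.94 to 3.96). In 4-month Cre+ replicate 2, Lyz2 was at 8.04 (8.33 to 8.37), and in replicate 3 Gpx6 was at 8.26 (8.88 to 8.97). Among 7-month Cre+ arrays, replicate 4 had Dnase1 at 7.39 (8.10 to 8.17), Fgg at 8.86 (9.80 to 9.93) and Insrr at 5.69 (5.15 to 5.20). Replicate 2 of that group had Calb1 at 8.38 (9.15 to 9.20) and Flt1 at 6.61 (7.20 to 7.27), and replicate 1 had Cyp2d12 at 7.06 (5.95 to 6.13). In 4-month Cre- replicate 1, Insrr was at 6.10 (6.71 to 6.78).

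Table entries without a single gene symbol, 17824 in number, were outside the comparisons. Of these 60 were higher and 14 lower in Cre+ kidneys at 4 months, and 692 were higher and 325 lower at 7 months.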

How the results depend on the processing

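Fits within arrays of high or low Y-linked values were chosen after the data were seen. Of 211 results on named genes, none reversed under the alternatives fixed before the data were examined or without 1 array, and the call was lost for 0 to 20 by setting. Genes lower at 4 months numbered 268 with the filter on dim genes, 280 with quantile normalization, 435 with median centring, 324 with the Y-linked covariate, 109 over all entries and 47 in the arrays with low Y-linked values, and genes higher 272 in those with high values. At 7 months 1537 were higher in the arrays with high and 1225 lower in those with low Y-linked values. In the interaction the plain linear model gave 90 higher and 137 lower genes, all entries 124 and 97, and the Y-linked covariate 433 lower. For age in Cre- kidneys the plain linear model, the 2 groups only, the replicate block and all entries each gave 0 higher genes, and lists called were 3 with the filter on dim genes, 3 with 2 groups only, 2 with array weights and 2 with the Y-linked covariate. With an estimated correlation 2 lists were called at 4 months, 6 at 7 months, 2 in the interaction, 0 for age in Cre- and 4 for age in Cre+ kidneys. In the same order, fry called 12, 17, 10, 0 and 16. The correlation of the Cre effects was 0.826 with the filter on dim genes. Slc7a12 at 7 months was at 1.25 over all arrays (SE 1.26, adjusted p = 0.54) and at -1.01 in a fit of the arrays with low Y-linked values (adjusted p = 0.0091), where 1 array was the only control. With the Y-linked covariate the calls shared with the fit without it were 784 of 784 at 4 months, 4924 of 4991 at 7 months and 475 of 475 in the interaction. Fewer arrays enter the fits within Y-linked levels. For the other changes the cause was not tested.

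The replicate block gave 614 higher and 181 lower genes at 4 months, 2398 and 2329 at 7 months, 185 and 233 in the interaction and 909 and 1445 for age in Cre+ kidneys. Of 21 pairs of arrays with the same number 11 deviated together at r over 0.1, with a range of -0.47 to 0.30. All 4 pairs of the 4-month and 7-month Cre+ groups did (0.17 to 0.30), but replicates 1 and 2 had high and 3 and 4 low Y-linked values in both groups. There, arrays of different numbers with the same Y-linked level had r of 0.18 to 0.37, not every array correlated best with its own number, and without the Y-linked level the 4 pairs had r of -0.08 to 0.08, so the shared deviation goes with that level and not with the number. The block changed no call of a named gene or list for age in Cre+ kidneys.

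Leaving out each array in turn gave 370 to 904 higher and 72 to 197 lower genes at 4 months, with 384 and 86 without Cre- replicate 1, 385 and 84 without Cre- replicate 3, 72 lower without Cre+ replicate 2, 373 and 96 without Cre+ replicate 3, and 370 higher without Cre+ replicate 4. At 7 months the ranges were 1846 to 2826 and 1867 to 2456. In the interaction they were 108 to 228 and 117 to 288, with 121 and 140 without 4-month Cre- replicate 2, 162 lower without 4-month Cre- replicate 4, 128 and 148 without 4-month Cre+ replicate 1, 163 lower without 4-month Cre+ replicate 4, 108 and 117 without 7-month Cre- replicate 2, 148 lower without 7-month Cre- replicate 3, 149 without 7-month Cre+ replicate 2 and 156 without 7-month Cre+ replicate 3. For age in Cre+ kidneys they were 604 to 949 (lowest without 4-month Cre+ replicate 1) and 956 to 1523, with 959 without 4-month Cre+ replicate 4 and 956 without 7-month Cre+ replicate 2. For age in Cre- kidneys 0 to 1 genes were higher, with 0 without any one Cre- array or without 7-month Cre+ replicate 1 or 4, and 0 to 4 lists were called, 4 without 4-month Cre- replicate 2, 0 without 4-month Cre- replicate 4 and 2 without any one 7-month Cre- array. The correlation of the Cre effects ranged from 0.697 (without 4-month Cre- replicate 3) to 0.758.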

Other observations

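The gene groups in this part were chosen after the data were seen, so their counts are descriptions and no list test was run on them. Of 21 pigment cell and melanosome genes, 9 rose and 1 fell at 4 months and 10 rose and 1 fell at 7 months. Besides Tyrp1, the melanosome receptor Gpr143 rose by 2.84 (SE 0.17) and 3.16 (SE 0.18), which may be lower bounds since its control mean of 3.76 may not be above background, Mreg by 2.70 (SE 0.23) and 3.52 (SE 0.24), the endolysosomal channel gene Mcoln3 by 2.34 (SE 0.18) and 2.71 (SE 0.20), Trpm1 by 1.45 (SE 0.19) and 2.12 (SE 0.21), and Kit, a receptor kinase, by 0.91 (SE 0.14) and 1.51 (SE 0.16). Mitf stood at -0.17 (SE 0.15) and -0.26 (SE 0.16), and Pmel and Mlana passed the test at neither age. Tyr, the enzyme that starts melanin synthesis, Dct and Sox10 did not pass either, but their control means of 3.07, 3.51 and 3.70 may not be above background, so nothing is read from them. Rab38 fell by 0.49 (SE 0.13) and 0.69 (SE 0.14).

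Of 9 MHC class II genes 5 rose at 4 months and 7 at 7 months, with medians of 0.51 and 1.16, and H2-Ab1 rose by 1.14 (SE 0.15) and 2.00 (SE 0.16). Of 14 acute phase genes 3 rose at 4 months and 7 at 7 months. The 7-month values were 2.46 (SE 0.26) for Cp, ceruloplasmin, 2.43 (SE 0.24) for Serpina3n and 2.05 (SE 0.18) for Lbp, whereas Hp stood at 0.06 (SE 0.22). Saa3 had a control mean of 3.86, too dim for its value to be read. Of 16 organic ion transporters of the proximal tubule 0 passed limma's test at 4 months, with a median of -0.31, and 13 fell at 7 months, with a median of -1.41. Of 21 immunoglobulin genes, whose probes can share sequence, 0 passed at 4 months (median 0.73) and 11 rose at 7 months (median 1.64).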
